A study of Homo sapiens with 15 samples.

How the data were processed

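Total RNA from 15 SKBR3 cultures (5 groups of 3) was measured on 1-colour (Cy3) Agilent arrays, 1 array per sample. Groups and replicate numbers were taken from the sample labels. The scanner software was Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes, and the array design was annotated on hg19, per the file headers. The scanner files deposited by the authors hold intensity values on a linear scale. Per the file headers, the processed signal in them was background-subtracted and detrended within each array by the software and was not scaled between arrays. The authors also deposited 1 table of log2 values, with 15 columns, all matched to a sample by name. Set against the scanner values, each column was the log2 processed signal less its 75th percentile, with an offset of 0.28 to 0.35 that was constant within an array and r = 1. Its scale, centring and direction were found that way, and are otherwise not given in the sources used here. The column medians lay between -3.86 and -3.49.

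From the scanner files, log2 of the processed signal less the array's 75th percentile over non-control probes was computed. Control spots were left out, and spots marked as non-uniform or population outliers were set to missing. Of 61657 non-control spots, those of a probe were averaged to 50683 probes, and a probe counted as well above background if at least 0.5 of its spots did. Probes were kept if well above background on all 3 arrays of at least 1 group, which left 17368, and 15 with a missing value were left out. RefSeq accessions of the probes were named through a gene table of GRCh38.p14, used for names only. It matched 28174 probes to 20503 symbols. Probes without a match were left out of gene counts. The kept probe with the highest mean over all arrays stood for a gene, which gave 13105 genes. The number of arrays limits the precision.

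Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) over all 15 arrays, with 1 coefficient per group, 10 residual and 3.05 prior degrees of freedom, and Benjamini-Hochberg adjustment per comparison at an adjusted p of 0.05. The comparisons were labelled against unlabelled for each antibody, each of the 4 antibodies against untreated cells, NLS-L against plain antibody with and without label, and the difference between both label effects. The design, the gene lists, the rule for named genes and the other settings were set before the data were examined.

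The 28 gene lists had 812 entries, 690 of them measured. Of these, 1 is not reported here. The other 27 were damage signalling, double-strand break repair, excision repair, replication-dependent histones, G1/S and replication, G2/M and mitosis, cyclin-dependent kinase inhibitors and quiescence, apoptosis, interferon-stimulated genes, antigen presentation, NF-kB targets and secreted inflammatory factors, NRF2 targets, heat shock, unfolded protein and integrated stress response, hypoxia, cholesterol biosynthesis, fatty acid synthesis, metallothioneins, lysosome, nuclear transport, ERBB receptors and ligands, ERK pathway output, FOXO targets, the HER2 amplicon, luminal and epithelial genes, mesenchymal genes, and markers of blood and endothelial cells. Each was tested with cameraPR on the moderated statistic at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The estimated correlation (camera) and fry were alternatives. The named genes of a comparison were those past the threshold with groups that did not overlap. From them the 8 largest rises and the 8 largest falls were taken, up to 3 more each way as bounds, and up to 4 members with the smallest p of each list that was called or had at least 3 members past the threshold. Where fewer than 3 genes passed, the 3 smallest p each way were given as not passed (5 for the difference of label effects), and ERBB2 and CDKN1A were always included. The rule gave 281 genes, of which the text names the ones that answer each comparison.

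A probe well above background on all arrays of one group and on none of the other gives a bound. It is the bright group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest value among probes well above background. Slides and scan batches were read from the file headers and were identical, so 1 block covers both. The replicate numbers were checked for pairing from the data, since the labels do not say what a shared number means. Deviations from the group means correlated above 0.1 for each number for labelled against unlabelled trastuzumab (0.316, 0.182 and 0.554 for numbers 1 to 3), unlabelled NLS-L antibody against untreated (0.303, 0.171 and 0.107), labelled NLS-L antibody against labelled trastuzumab (0.102, 0.290 and 0.261) and unlabelled NLS-L antibody against unlabelled trastuzumab (0.288, 0.268 and 0.428), where numbers were taken to pair the arrays. Other settings, chosen in advance, were other scalings (quantile, median centring, normexp with an offset of 50 followed by quantile), the deposited table, other probe filters, marked spots kept, the mean of a gene's probes, eBayes with trend and robust, array weights, only the groups compared, a threshold of 0.01, slide and replicate number as blocks, and each array left out in turn. The mean spot signal that normexp was planned on is not among the columns used here, and the median spot signal took its place. Single slides, replicate number 3 left out of all groups, and both arrays of low signal left out were added after seeing the data.

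The fit was tested on 5 simulated sets of 13105 genes with 200 seeded per labelled group. For the label on the NLS-L antibody, 38.8%, 75.7% and 97.0% of genes changed 1.5-, 2- and 4-fold were recovered. The shares were 38.6%, 80.2% and 95.1% for the label on trastuzumab, and 20.5%, 58.7% and 90.6% for the difference of both. False calls made up 5.64%, 4.56% and 5.19% of calls. A list shift seeded in the labelled NLS-L group was called in 5 of 5 sets in the first and last comparison. Unshifted lists were called 1, 0 and 0 times, and 3 times for labelled NLS-L against untreated. Real genes and arrays correlate, so real error rates may differ.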

Results

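SKBR3, an established breast cancer cell line that carries many copies of ERBB2 (the gene for the receptor HER2), was profiled on 15 one-colour Agilent arrays in 5 groups of 3. One group was left in medium alone (untreated) and the others were given an antibody for 7 days. Trastuzumab is an antibody against HER2. It was used as such, in a form the labels call NLS-L without spelling the name out, and in both forms carrying In-111, a radionuclide that emits short-range Auger electrons. The labels give 231.25 MBq for both In-111 groups without saying per what. The study asked which transcriptional changes follow Auger electron treatment when the labelled antibody is directed to the nucleus. The antibodies are called labelled or unlabelled trastuzumab and labelled or unlabelled NLS-L antibody here. The 75th percentile of the array signal lay between 138 and 208 units except on untreated replicate 2 (94.1) and unlabelled NLS-L replicate 3 (99.6), and 40.7% to 47.9% of probes were well above background. The labels describe 3 independent experiments per condition, and the p-values measure only the spread between these arrays.

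The 2 slides were each scanned as 1 batch. Slide 1 held 8, all untreated and labelled trastuzumab arrays and 2 of unlabelled trastuzumab. Slide 2 held 7, unlabelled trastuzumab replicate 3 and all NLS-L arrays. A fit with slide as a block separates slide from group only through unlabelled trastuzumab, whose replicate 3 moved with other replicate 3 arrays. Across slides the fit cannot tell slide from that swing. Changes are given as log2 fold changes ± standard error from limma (n = 3 arrays per group), with p-values adjusted over the 13105 genes tested. Genes were named as changed only where all 3 arrays of one group lay above all 3 of the other. Gene groups are 28 lists fixed in advance, and the p-value of a list is that of limma's camera test adjusted over the lists, likewise where given with an estimated correlation. Median centring shifted all list medians of a comparison alike, by -0.069 for the label on trastuzumab, 0.24 for the difference of label effects, 0.0097 and 0.079 for labelled and unlabelled trastuzumab and -0.043 for unlabelled NLS-L antibody against untreated cells, and by the amounts given below in the others. Medians with normexp or quantile scaling are given where they moved by over 1.5 times, and calls held there unless stated. Of 93 list calls over all comparisons, 3 held when the correlation between members was estimated.

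**Figure D1:**
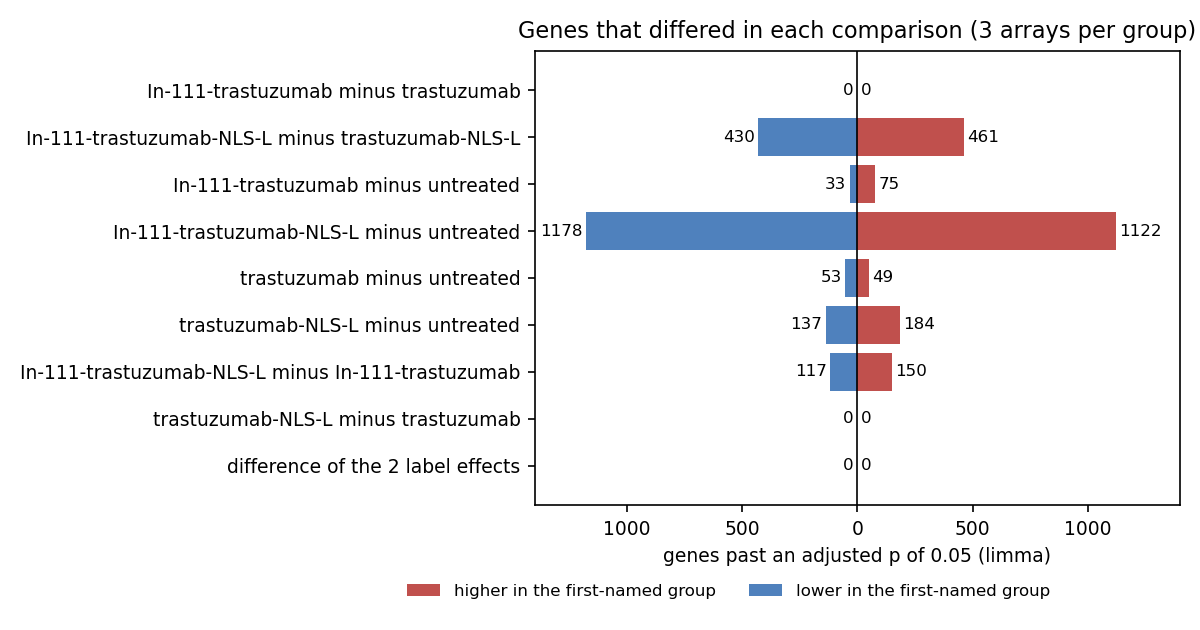
Number of genes past an adjusted p of 0.05 in limma in each comparison (horizontal axis, 3 arrays per group), with genes higher in the first-named group to the right and genes lower in it to the left. The labelled NLS-L antibody differed from untreated cells in 1122 higher and 1178 lower genes, and 0 genes passed for the label on trastuzumab. With median centring the share of higher genes rose from 51.7% to 92.4% for the label on the NLS-L antibody and from 48.8% to 76.1% for the labelled NLS-L antibody against untreated cells.

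Labelled against unlabelled NLS-L antibody asked what the radionuclide added on the nuclear-directed antibody, and all 6 arrays lay on slide 2. With the label, the lists of inflammatory and interferon-stimulated genes were higher, and those of fatty acid synthesis and metallothioneins were lower (adjusted p = 0.285, 0.295, 0.428 and 0.428 with an estimated correlation). The cytokine IL6 was at least 10.9-fold higher (adjusted p = 0.00491), its probe being well above background only with the label. SAA1, an acute-phase protein, rose by 2.22 ± 0.31 (adjusted p = 0.00359). INSL4, an insulin-like peptide of the placenta, rose by 2.92 ± 0.23 (adjusted p = 1.34e-04) and TAC3, the neurokinin B precursor, by 3.02 ± 0.49 (0.00640). The keratin pseudogene KRT16P2 rose by 2.93 ± 0.43 (adjusted p = 0.00481), with KRT17, a keratin of stressed epithelia, at 3.74 ± 0.68 (0.0102, and 0.0585 without labelled NLS-L replicate 1). The KRT17 probe was well above background on 3 labelled arrays and 1 unlabelled one. Probes of these keratins, like those of SAA1 with SAA2, can bind near-identical family members. Genes that fell included RSPO4, a Wnt pathway agonist (-1.63 ± 0.22, adjusted p = 0.00283). COL4A5, a basement membrane collagen chain, was at least 2.56-fold lower (adjusted p = 0.00507). ERBB2 itself had a change of -0.41 ± 0.09 (adjusted p = 0.0233), and its adjusted p was 0.0925, 0.0721 and 0.0503 without labelled NLS-L replicates 1, 2 and 3, 0.0945 without unlabelled NLS-L replicate 2. With median centring it had -0.24 (adjusted p = 0.244).

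By list, NF-kB targets and secreted inflammatory factors had the highest median with the label on the NLS-L antibody. It was 1.13, with 14 of 28 measured members higher, 20 when adjusted over the list alone, and none lower (adjusted p = 1.57e-16 and p = 0.285 with an estimated correlation). Besides SAA1 and IL6, the chemokine CCL28 rose by 1.79 ± 0.28 (adjusted p = 0.00607) and SOD2, the mitochondrial superoxide dismutase, by 1.15 ± 0.19 (0.00760). Interferon-stimulated genes had a median of 0.54, with 8 of 26 higher, 12 adjusted over the list alone (adjusted p = 1.42e-06 and p = 0.295 with an estimated correlation). Antigen presentation had a median of 0.29, with 3 of 22 higher, 5 adjusted over the list alone (adjusted p = 0.00104 and p = 0.428 with an estimated correlation). Fatty acid synthesis and storage had a median of -0.30, with 5 of 23 lower, 9 adjusted over the list alone (adjusted p = 4.35e-04 and p = 0.428 with an estimated correlation). Metallothioneins, which bind zinc and copper, had a median of -0.93 and a mean of -0.47, with 6 of 11 lower, and 1 higher and 7 lower adjusted over the list alone (adjusted p = 0.00386 and p = 0.428 with an estimated correlation). Probes of this family can bind several members. Normexp gave 0.66 for the NF-kB and 0.23 for the interferon list, and median centring gave -0.13 for fatty acid synthesis.

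Further lists passed in labelled against unlabelled NLS-L antibody, each call being lost without at least 1 array. Cholesterol biosynthesis had 1 of 24 members lower, 4 adjusted over the list alone (median -0.17, adjusted p = 0.0110 and p = 0.428 with an estimated correlation). With median centring the median was -0.00069. This call was lost at -0.12 without labelled NLS-L replicate 3, -0.09 without unlabelled NLS-L replicate 1. The member that fell was INSIG1, a sterol-regulated protein of the endoplasmic reticulum (-0.81 ± 0.14, adjusted p = 0.00927, and 0.0521 without labelled NLS-L replicate 1). The heat shock response had 2 of 21 members higher, 2 adjusted over the list alone (median 0.27, adjusted p = 0.00789 and p = 0.428 with an estimated correlation). The list was lost at 0.17 without unlabelled NLS-L replicate 3. The hypoxia response had 4 of 23 lower, 7 lower and 1 higher adjusted over the list alone, with a median of -0.12 that turned to 0.04 with median centring (adjusted p = 0.0408 and p = 0.428 with an estimated correlation). Its call was lost at -0.07 and -0.09 without labelled NLS-L replicates 1 and 2, -0.12 without unlabelled NLS-L replicate 2. Cyclin-dependent kinase inhibitors and quiescence genes had 0 of 20 members past the threshold and 0 adjusted over the list alone (median 0.23, adjusted p = 0.0408 and p = 0.285 with an estimated correlation). This call was lost at 0.19 without labelled NLS-L replicate 3, 0.19 without unlabelled NLS-L replicate 2. Lysosomal genes had 3 of 29 higher, 4 adjusted over the list alone (median 0.12, adjusted p = 0.0408 and p = 0.428 with an estimated correlation). The list was lost at 0.12 and 0.11 without labelled NLS-L replicates 1 and 3, 0.12 and 0.20 without unlabelled NLS-L replicates 2 and 3. Mesenchymal genes had 1 of 7 higher, 2 adjusted over the list alone (median 0.44, adjusted p = 0.0408 and p = 0.428 with an estimated correlation). Its call was lost at 0.43 without labelled NLS-L replicate 3, 0.46 without unlabelled NLS-L replicate 1. FOXO targets had 2 of 25 higher, 3 adjusted over the list alone (median 0.21, adjusted p = 0.0488 and p = 0.428 with an estimated correlation). This call was lost at 0.16 and 0.28 without labelled NLS-L replicates 1 and 3, 0.24 and 0.15 without unlabelled NLS-L replicates 2 and 3. Slide 2 alone ended the lysosome call (adjusted p = 0.0643), and a fit with slide as a block ended the mesenchymal one (adjusted p = 0.0501). Normexp ended the FOXO (0.12), lysosome and mesenchymal (0.29) calls and quantile scaling the FOXO, lysosome and kinase inhibitor ones. Median centring ended the FOXO and hypoxia calls.

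In lists of DNA repair, damage signalling and the cell cycle, few or no members passed with the label on the NLS-L antibody. The probe of CDKN1A, a cyclin-dependent kinase inhibitor, was well above background on 2 of 15 arrays and was not tested. Of the members measured, 0 of 33 double-strand break repair genes (median 0.00, adjusted p = 0.801), 0 of 23 damage signalling genes (0.05, 0.801), 0 of 43 G1/S genes (-0.02, 0.801) and 0 of 39 mitotic genes (-0.01, 0.975) passed limma's test, and 0 did in these 4 lists adjusted over the list alone. Base and nucleotide excision repair (-0.07, 0.793), nuclear transport (0.05, 0.801), the unfolded protein and integrated stress response (-0.02, 0.801) and ERK pathway output (-0.02, 0.715) each had 1 lower member and did not pass. Apoptosis regulators had 4 of 30 members higher (0.08, 0.123), the HER2 amplicon 2 of 18 lower (-0.09, 0.0837), markers of blood and endothelial cells 2 of 13 higher (0.24, 0.158) and replication-dependent histones 1 of 21 higher (-0.01, 0.900), and these lists did not pass. ERBB receptors and ligands (0.11, 0.801), NRF2 targets (-0.04, 0.789) and luminal and epithelial genes (-0.08, 0.975) each had 1 member higher and 1 lower. The median, mean or test differed in sign for the last 3 lists and for mitotic genes, histones and the unfolded protein response.

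In all, 891 genes differed between labelled and unlabelled NLS-L antibody, 461 higher and 430 lower (limma). With median centring, which moved the median of all genes by 0.17, 92.4% of the changed genes were higher in place of 51.7%. The count was 94 without labelled NLS-L replicate 1, 223 without its replicate 2, 454 without unlabelled NLS-L replicate 1 and 180 without its replicate 2. It was 1341 with slide as a block and 373 from slide 2 alone. As both groups lay on slide 2, these settings left the fold changes as they were and do not test slide.

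**Figure D2:**
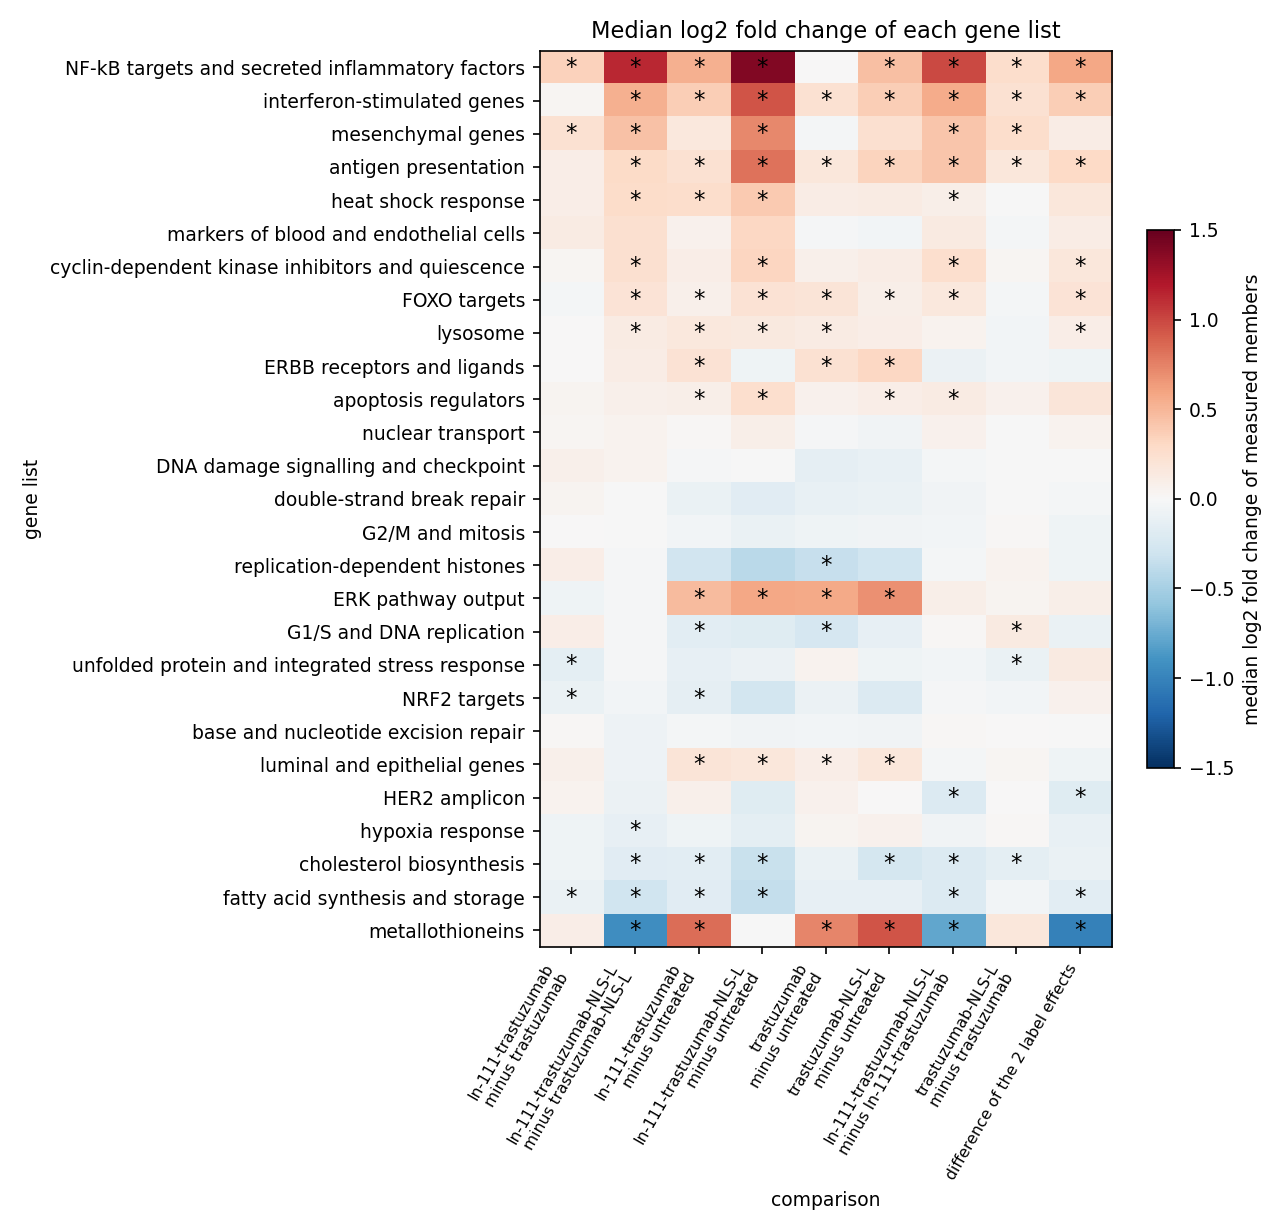
Median log2 fold change of the measured members of 27 gene lists (vertical axis) in each comparison (horizontal axis), with colour from lower (blue) to higher (red) and a star for an adjusted p under 0.05 in camera. The NF-kB list stood at 1.13 and the metallothioneins at -0.93 for the label on the NLS-L antibody, where the hypoxia list turned to 0.04 with median centring. In the difference of both label effects, the HER2 amplicon and fatty acid lists turned to 0.05 and 0.08 with median centring, and with slide as a block metallothioneins turned to 0.20 for labelled NLS-L antibody against labelled trastuzumab.

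**Figure D3:**
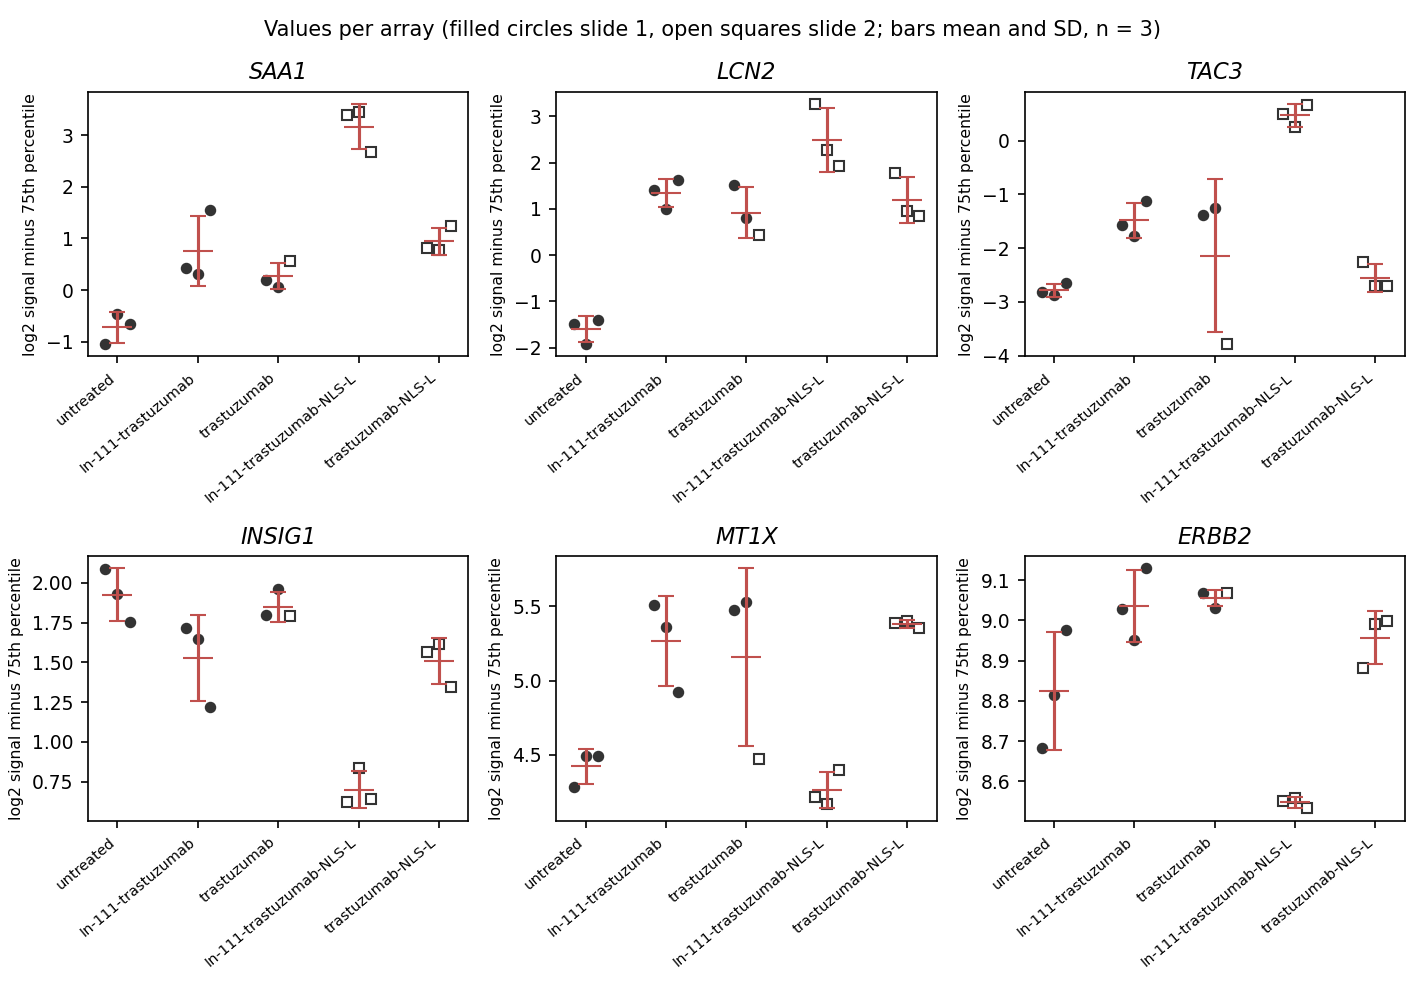
Log2 signal minus the array's 75th percentile (vertical axis) of 6 genes on each array of the 5 groups (horizontal axis), with filled circles for slide 1, open squares for slide 2, and bars for the mean and SD (n = 3). With labelled NLS-L antibody SAA1, LCN2 and TAC3 lay above the unlabelled NLS-L arrays, and INSIG1, MT1X and ERBB2 below them, ERBB2 by -0.41 and by -0.24 with median centring.

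The same question for trastuzumab without NLS-L, labelled against unlabelled, gave 0 genes past the threshold in limma, with 604 at an unadjusted p under 0.05 (889 with the replicate number as a block, 1528 with array weights). The smallest p-value belonged to NMT2, an N-myristoyltransferase (log2 fold change -1.02 ± 0.16, adjusted p = 0.383). Inflammatory genes had positive values that did not pass, with CCL28 at 1.46 ± 0.28, adjusted p = 0.828 and IL6 at 1.82 ± 0.56 (0.948). As a list, the NF-kB list was higher, with a median of 0.34, 26 of 28 members positive, 0 past the threshold and 1 adjusted over the list alone (adjusted p = 7.60e-07 and p = 0.886 with an estimated correlation). The median was 0.20 with normexp and 0.54 from slide 1 alone (adjusted p = 1.18e-11) and the call was lost at 0.13 without labelled trastuzumab replicate 3. Mesenchymal genes (0.23, adjusted p = 0.0466 and p = 0.886 with an estimated correlation) were higher, with 7 of 7 members positive, and were lost at 0.04 without labelled trastuzumab replicate 3, 0.10 and 0.21 without unlabelled trastuzumab replicates 1 and 2. They stood at 0.38 from slide 1 alone (adjusted p = 1.73e-04). Fatty acid synthesis had a median of -0.10 with 16 of 23 members negative (adjusted p = 0.0466 and p = 0.886 with an estimated correlation), an adjusted p of 0.0973 with the replicate number as a block and 0.124 from slide 1 alone (median -0.14). The list was lost at -0.06 without labelled trastuzumab replicate 3, -0.10 and -0.14 without unlabelled trastuzumab replicates 1 and 3. The unfolded protein response (-0.15, 24 of 31 negative, adjusted p = 0.0101 and p = 0.886 with an estimated correlation) and NRF2 targets (-0.10, 20 of 24 negative, adjusted p = 0.0466 and p = 0.886 with an estimated correlation) turned to 0.08 and 0.05 with slide as a block, from slide 1 alone and without unlabelled trastuzumab replicate 3. Their calls were also lost without labelled trastuzumab replicate 1 (-0.16 and -0.08) and replicate 2 (-0.11 and -0.08). In these 4 lists 0 members passed, and 0 adjusted over the list alone. None of the 4 passed without replicate number 3 in any group (adjusted p from 0.0898), and quantile scaling ended the calls of all but the unfolded protein response. Median centring and the deposited values ended the fatty acid call, and normexp the mesenchymal one. ERBB2 had a value of -0.02 ± 0.09, adjusted p = 0.990. Array weights gave 7 changed genes, and slide 1 alone gave 0 (424 at an unadjusted p under 0.05).

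Whether the label acted differently on the 2 antibodies was tested as the difference between both label effects. The gene with the smallest p-value was INSL4, with a label effect higher by 2.39 ± 0.33 on the NLS-L antibody (adjusted p = 0.0714, and 0.0333 with slide as a block). ERBB2 had -0.39 ± 0.13, adjusted p = 0.607. By this test 0 genes passed in limma, with 887 at an unadjusted p under 0.05, 2 with slide as a block, 17 without replicate 3 of all groups and 1055 with array weights. Lists did differ. The NF-kB list had a difference of 0.58 with 26 of 28 members positive (adjusted p = 5.66e-09 and p = 0.346 with an estimated correlation), and interferon-stimulated genes one of 0.37 with 20 of 26 positive (adjusted p = 2.99e-06 and p = 0.346 with an estimated correlation). Metallothioneins had a difference of -1.01 with 8 of 11 negative (adjusted p = 1.09e-05 and p = 0.346 with an estimated correlation). In the fit blocked by slide, these 3 medians were 0.46, 0.29 and -0.65 (adjusted p = 1.91e-05, 1.34e-04 and 1.27e-04). Across genes, which are not independent replicates, both label effects correlated at r = 0.501 (Spearman 0.462, covariance 0.0443). They share no array, but same-numbered arrays deviated together, from which a covariance of 7.21e-04 was estimated with no effect. Swings that arrays share by chance are not in this estimate. Without labelled trastuzumab replicate 3, r was 0.30.

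Labelled NLS-L antibody against untreated cells was the full treatment against none. The acute-phase and innate defence genes S100A7 (psoriasin, 4.25 ± 0.42, adjusted p = 7.01e-05), LCN2 (lipocalin, 4.10 ± 0.36, 3.52e-05) and SAA1 (3.89 ± 0.31, 2.72e-05) rose, as did the complement protease C1S (3.82 ± 0.33, 3.52e-05). CGA, the alpha chain of the glycoprotein hormones, rose by 3.73 ± 0.36 (adjusted p = 6.28e-05). PIGR, the polymeric immunoglobulin receptor, was at least 12.2-fold higher (adjusted p = 5.71e-05) and IL6 at least 9.81-fold (3.16e-04). RASSF2, a Ras-association protein, fell (-2.07 ± 0.32, adjusted p = 0.00104). ERBB2 stood at -0.28 ± 0.09, adjusted p = 0.0543. Probes of S100A7 can bind S100A7A.

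Of the NF-kB list, 21 of 28 were higher with labelled NLS-L antibody than in untreated cells, 24 adjusted over the list alone (median 1.39, adjusted p = 1.33e-23 and p = 0.109 with an estimated correlation). Interferon-stimulated genes had 17 of 26 higher, 20 adjusted over the list alone (median 0.94, adjusted p = 1.99e-17 and p = 0.0474 with an estimated correlation), with ISG15, a ubiquitin-like modifier, at 1.92 ± 0.19, adjusted p = 7.01e-05. Antigen presentation had 12 of 22 higher, and 14 higher and 1 lower adjusted over the list alone (median 0.81, adjusted p = 1.07e-10 and p = 0.124 with an estimated correlation). Cholesterol biosynthesis had 10 of 24 lower, 11 adjusted over the list alone (median -0.34, adjusted p = 3.52e-06 and p = 0.151 with an estimated correlation), with INSIG1 at -1.22 ± 0.14, adjusted p = 1.86e-04. Fatty acid synthesis had 12 of 23 lower, 14 adjusted over the list alone (median -0.36, adjusted p = 3.64e-05 and p = 0.151 with an estimated correlation). Cyclin-dependent kinase inhibitors and quiescence genes had 5 of 20 higher, 6 adjusted over the list alone (median 0.33, adjusted p = 0.00124 and p = 0.0474 with an estimated correlation), with TXNIP, a thioredoxin inhibitor, at 2.39 ± 0.25, adjusted p = 8.06e-05. The heat shock response (6 of 21 higher, median 0.40, adjusted p = 5.10e-04 and p = 0.316 with an estimated correlation) and luminal and epithelial genes (9 higher and 3 lower of 30, median 0.17, adjusted p = 0.00139 and p = 0.124 with an estimated correlation) also passed, with 6 higher in the first and 12 higher and 5 lower in the other adjusted over the list alone. Blocked by slide, medians of these 8 lists were 0.80, 0.75, 0.29, -0.26, -0.45, 0.28, 0.66 and 0.29, and all 8 calls held (highest adjusted p = 0.0444). Normexp gave 0.82, 0.49 and 0.26 for the NF-kB, interferon and luminal lists (luminal 0.27 with quantile scaling).

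Apoptosis regulators passed as higher against untreated cells (10 of 30, and 11 higher and 1 lower adjusted over the list alone, median 0.25, adjusted p = 7.43e-04 and p = 0.117 with an estimated correlation). ERK pathway output (5 of 21 higher, 5 adjusted over the list alone, median 0.58, adjusted p = 0.00102), FOXO targets (9 higher and 1 lower of 25, the same counts adjusted over the list alone, median 0.22, adjusted p = 1.79e-04), lysosomal genes (6 of 29 higher, 8 adjusted over the list alone, median 0.15, adjusted p = 0.00263) and mesenchymal genes (4 of 7 higher, and 5 higher and 1 lower adjusted over the list alone, median 0.73, adjusted p = 0.0183) passed as well. In this order, adjusted p = 0.297, 0.163, 0.162 and 0.401 with an estimated correlation. The mesenchymal median was 0.34 with normexp, and its call was lost at 0.62 without labelled NLS-L replicate 3. With slide as a block these 5 medians were 0.20, 0.07, 0.06, 0.06 and 0.34 and none passed (adjusted p = 0.386, 0.822, 0.835, 0.137 and 0.822). CD68, a macrophage marker also found in lysosomes of other cells, rose by 2.29 ± 0.30, adjusted p = 3.61e-04 (and 0.0593 with slide as a block), in a list of markers of blood and endothelial cells that had 3 of 13 members higher and 1 lower and did not pass (median 0.31, adjusted p = 0.0886). In all, 2300 genes differed (1122 higher, 1178 lower). Median centring, which moved the median of all genes by 0.12, gave 76.1% higher in place of 48.8%. The count was 1487 without untreated replicate 2, 1420 without untreated replicate 3, 1109 without labelled NLS-L replicate 1 and 1476 without its replicate 2. It was 1227 with slide as a block, of which 592 were among the 2300, and no slide held both groups.

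Trastuzumab against untreated cells asked what the antibody changed without label or NLS-L. LCN2 rose by 2.52 ± 0.36, adjusted p = 0.00651, PLAAT4, a phospholipase and acyltransferase, by 2.49 ± 0.30 (0.00344), TXNIP by 1.90 ± 0.25 (0.00432) and KRT23, a keratin, by 1.56 ± 0.16 (0.00167). PIGR was at least 3.51-fold higher (adjusted p = 0.00651). DIO2, a deiodinase that activates thyroid hormone, fell (-1.41 ± 0.19, adjusted p = 0.00513). ERBB2 had a value of 0.23 ± 0.09, adjusted p = 0.265. ERK pathway output had 1 of 21 members higher, 3 adjusted over the list alone (median 0.57, adjusted p = 1.22e-06 and p = 0.316 with an estimated correlation). Metallothioneins had 0 of 11 past the threshold and 7 higher adjusted over the list alone (median 0.74, adjusted p = 9.19e-05 and p = 0.393 with an estimated correlation). Luminal and epithelial genes (2 of 30 higher, and 6 higher and 1 lower adjusted over the list alone, median 0.10, adjusted p = 3.00e-04 and p = 0.118 with an estimated correlation) and interferon-stimulated genes (0 of 26, 0 adjusted over the list alone, median 0.23, adjusted p = 9.19e-05 and p = 0.316 with an estimated correlation) also passed. From slide 1 alone the medians of these 4 lists were 0.32, 1.08, 0.16 and 0.17, equal to those with slide as a block, and all 4 passed. Normexp gave 0.34 for the ERK and 0.14 for the interferon list.

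Other lists called for trastuzumab against untreated cells lost their calls without its replicate 3, the array on slide 2. G1/S and DNA replication had a median of -0.25 with 0 of 43 past the threshold and 2 lower adjusted over the list alone (adjusted p = 0.00291 and p = 0.842 with an estimated correlation), and of 0.09 without that array, from slide 1 alone or with slide as a block. Replication-dependent histones went from -0.35 (0 of 21, and 0 adjusted over the list alone, adjusted p = 0.0186 and p = 0.842 with an estimated correlation) to -0.02 in the same settings, and were lost at -0.27 without untreated replicate 2. FOXO targets (3 of 25 higher, and 5 higher and 1 lower adjusted over the list alone, adjusted p = 8.19e-04 and p = 0.393 with an estimated correlation) went from 0.20 to 0.02 and antigen presentation (1 of 22 higher, 1 adjusted over the list alone, adjusted p = 0.00854 and p = 0.615 with an estimated correlation) from 0.17 to 0.06, and neither passed (adjusted p = 0.142 and 0.271 with slide as a block). ERBB receptors and ligands (1 of 17 higher, 1 adjusted over the list alone, median 0.23, adjusted p = 0.0216 and p = 0.249 with an estimated correlation) and lysosomal genes (0 of 29, 0 adjusted over the list alone, median 0.13, adjusted p = 0.0283 and p = 0.393 with an estimated correlation) passed over all 15 arrays and not with slide as a block (0.23 and 0.12, adjusted p = 0.0622 and 0.0880). The ERBB median was 0.13 with normexp and the lysosome median 0.19 with quantile scaling. Without trastuzumab replicate 3, FOXO targets were lost at 0.02 and the ERBB list at 0.23. Antigen presentation was lost at 0.16 without untreated replicate 3, 0.06 without unlabelled trastuzumab replicate 3, and lysosomal genes at 0.06 and 0.17 without untreated replicates 2 and 3, 0.13 and 0.12 without unlabelled trastuzumab replicates 2 and 3. In all, 102 genes differed (49 higher and 53 lower). Median centring gave 79.3% higher in place of 48.0%. The count was 16 without untreated replicate 1, 22 without untreated replicate 2, 34 and 58 without trastuzumab replicates 1 and 2, 44 from slide 1 alone and 127 with slide as a block, of which 71 were among the 102.

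In labelled trastuzumab against untreated cells, the antibody and its radionuclide without NLS-L, both groups lay on slide 1. Higher were LCN2 (2.95 ± 0.36, adjusted p = 0.00229), PLAAT4 (2.56 ± 0.30, 0.00178) and KRT23 (1.84 ± 0.16, 6.43e-04). PIP, the prolactin-induced protein, was at least 3.62-fold higher (adjusted p = 0.00721) and PIGR at least 2.97-fold (0.00889). ERBB2 had a value of 0.21 ± 0.09, adjusted p = 0.342. Luminal and epithelial genes had 3 of 30 higher, and 7 higher and 1 lower adjusted over the list alone (median 0.19, adjusted p = 8.04e-07 and p = 0.0318 with an estimated correlation). The NF-kB list had 2 of 28 higher, 7 adjusted over the list alone (median 0.53, adjusted p = 5.89e-09 and p = 0.205 with an estimated correlation), and ERK pathway output 2 of 21, 2 adjusted over the list alone (median 0.48, adjusted p = 2.03e-06 and p = 0.205 with an estimated correlation). Interferon-stimulated genes had 0 of 26 past the threshold and 8 higher adjusted over the list alone (median 0.37, adjusted p = 2.21e-07 and p = 0.170 with an estimated correlation). Metallothioneins had 0 of 11 and 7 higher adjusted over the list alone (median 0.84, adjusted p = 2.21e-07 and p = 0.205 with an estimated correlation). Antigen presentation had 1 of 22 higher, 4 adjusted over the list alone (median 0.22, adjusted p = 9.52e-06 and p = 0.205 with an estimated correlation). All 6 passed from slide 1 alone. Normexp gave 0.27, 0.32 and 0.19 for the NF-kB, ERK and interferon lists. Without replicate number 3 in any group, the NF-kB median was 0.20 (adjusted p = 0.00180) and antigen presentation was lost at 0.12 (adjusted p = 0.0695).

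Further lists passed for labelled trastuzumab against untreated cells in heat shock (0.26, adjusted p = 0.00144), ERBB receptors and ligands (0.21, adjusted p = 0.00437), FOXO targets (0.07, adjusted p = 0.0107) and lysosomal genes (0.16, adjusted p = 0.00665), and, as lower, in fatty acid synthesis (-0.17, adjusted p = 3.70e-04). In the order given, adjusted p = 0.350, 0.116, 0.356, 0.205 and 0.205 with an estimated correlation. The G1/S list (-0.15, adjusted p = 0.0275) was lost at -0.12 without untreated replicate 1, -0.02 without labelled trastuzumab replicate 3, cholesterol biosynthesis (-0.15, adjusted p = 0.00665) at -0.10 without untreated replicate 1, -0.06 without labelled trastuzumab replicate 3, NRF2 targets (-0.13, adjusted p = 0.00878) at -0.17 without labelled trastuzumab replicate 1 and apoptosis regulators (0.08, adjusted p = 0.0430) at 0.09 without untreated replicate 1, 0.07 and 0.09 without labelled trastuzumab replicates 2 and 3. In this order, adjusted p = 0.742, 0.350, 0.338 and 0.212 with an estimated correlation. Without replicate number 3 in any group, the G1/S, cholesterol, fatty acid, apoptosis and lysosome calls were lost (adjusted p = 0.557, 0.0706, 0.0769, 0.0839 and 0.0839). Normexp gave 0.064, 0.046 and -0.11 for the ERBB, FOXO and fatty acid lists. In these 9 lists, 3 FOXO targets and 1 ERBB list member passed. Adjusted over the list alone, 4 ERBB members, 4 FOXO targets, 3 apoptosis regulators and 2 lysosomal genes were higher, and 4 fatty acid genes and 1 FOXO target were lower. In all, 108 genes differed (75 higher and 33 lower), and median centring gave 88.5% higher in place of 69.4%. The count was 28 without untreated replicate 1, 22 without untreated replicate 2, and 70, 41 and 31 without labelled trastuzumab replicates 1, 2 and 3. It was 73 from slide 1 alone and 230 with slide as a block.

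Unlabelled NLS-L antibody against untreated cells asked what the carrier changed without radiation. Higher were TIMP1, a metalloproteinase inhibitor (2.33 ± 0.19, adjusted p = 1.09e-04), PLAAT4 (3.04 ± 0.30, 3.25e-04), LCN2 (2.80 ± 0.36, 0.00142), CGA (2.54 ± 0.36, 0.00310) and KRT23 (2.31 ± 0.16, 4.04e-05). PIGR was at least 5.30-fold higher (adjusted p = 9.50e-04). RASSF2 (-2.06 ± 0.32, 0.00484) fell, and ERBB2 had a value of 0.13 ± 0.09, adjusted p = 0.501. The slide block ended the calls of CGA (adjusted p = 0.0513) and PIGR (0.0614). ERK pathway output had 3 of 21 higher, 4 adjusted over the list alone (median 0.69, adjusted p = 2.63e-08 and p = 0.165 with an estimated correlation), led by SPRY4, a feedback inhibitor (1.47 ± 0.18, 9.78e-04). Interferon-stimulated genes had 4 of 26 higher, 9 adjusted over the list alone (median 0.37, adjusted p = 1.79e-09), antigen presentation 3 of 22, 6 adjusted over the list alone (median 0.34, adjusted p = 6.12e-07), and the NF-kB list 4 of 28, 7 adjusted over the list alone (median 0.45, adjusted p = 3.35e-06). In the order given, adjusted p = 0.110, 0.179 and 0.314 with an estimated correlation. Metallothioneins had 2 of 11 higher, 7 adjusted over the list alone (median 0.94, adjusted p = 3.35e-06 and p = 0.253 with an estimated correlation). Luminal and epithelial genes had 5 higher and 1 lower of 30, 7 and 1 adjusted over the list alone (median 0.17, adjusted p = 4.83e-06 and p = 0.0624 with an estimated correlation). In the fit blocked by slide, these 6 medians were 0.01, 0.29, 0.03, 0.06, 1.95 and 0.30 (adjusted p = 0.549, 0.0420, 0.706, 0.644, 2.04e-18 and 0.00340). Normexp gave 0.38, 0.21 and 0.18 for the ERK, interferon and NF-kB lists.

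Cholesterol biosynthesis was lower with unlabelled NLS-L antibody than in untreated cells (median -0.26, 0 of 24 past the threshold, 0 adjusted over the list alone, adjusted p = 6.00e-04 and p = 0.30 with an estimated correlation). Apoptosis regulators (3 of 30 higher, 3 adjusted over the list alone, median 0.10, adjusted p = 0.00467), FOXO targets (3 higher and 1 lower of 25, 4 and 1 adjusted over the list alone, median 0.09, adjusted p = 0.00376) and ERBB receptors and ligands (1 of 17 higher, 3 adjusted over the list alone, median 0.31, adjusted p = 0.0214) passed as higher. In this order, adjusted p = 0.165, 0.314 and 0.165 with an estimated correlation. The ERBB call was lost at 0.24 without untreated replicate 2, 0.24 without unlabelled NLS-L replicate 3. Blocked by slide, these 4 medians were -0.12, 0.12, -0.16 and 0.13, and none passed (adjusted p = 0.0780, 0.994, 0.119 and 0.401). Normexp gave 0.091 for the ERBB list and, like quantile scaling, 0.14 for FOXO targets. In all, 321 genes differed (184 higher and 137 lower). The count was 116 without untreated replicate 1, 115 without untreated replicate 2, and 161 and 168 without unlabelled NLS-L replicates 1 and 2. It was 648 with the replicate number as a block and 278 with slide as a block, of which 70 were among the 321, and no slide held both groups.

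Labelled NLS-L antibody against labelled trastuzumab asked what NLS-L added to the radiolabelled antibody, and the groups lay on different slides. SAA1 was higher by 2.40 ± 0.31, with an adjusted p of 0.00543 that became 0.0537 without labelled trastuzumab replicate 2. RSPO4 had a change of -1.46 ± 0.22 (adjusted p = 0.00959, and 0.0565 without labelled trastuzumab replicate 2, 0.0665 without labelled NLS-L replicate 1). ERBB2 was lower at -0.49 ± 0.09 (adjusted p = 0.0221, and 0.0724 and 0.0673 without labelled trastuzumab replicates 1 and 2, 0.10 and 0.0816 without labelled NLS-L replicates 1 and 2), and at -0.37 (adjusted p = 0.164) with median centring. With slide as a block RSPO4 passed (adjusted p = 0.0392), and SAA1 (1.97, adjusted p = 0.0922) and ERBB2 (-0.51, adjusted p = 0.121) did not. By list, the NF-kB list had 8 of 28 higher, 19 adjusted over the list alone (median 0.99, adjusted p = 2.87e-19 and p = 0.134 with an estimated correlation). Interferon-stimulated genes had 7 of 26, 14 adjusted over the list alone (median 0.55, adjusted p = 1.10e-13 and p = 0.0746 with an estimated correlation), and cholesterol biosynthesis had 1 of 24 lower, 2 adjusted over the list alone (median -0.21, adjusted p = 2.90e-05 and p = 0.243 with an estimated correlation). Fatty acid synthesis had 1 of 23 lower, and 1 higher and 7 lower adjusted over the list alone (median -0.21, adjusted p = 0.00726 and p = 0.409 with an estimated correlation). Its call was lost at -0.21 without labelled NLS-L replicate 3. In the fit blocked by slide, these 4 medians were 0.44, 0.23, -0.10 and -0.23, and all 4 passed (adjusted p = 0.00753, 0.00674, 0.0280 and 0.0324). The heat shock response (1 of 21 higher, 2 adjusted over the list alone, median 0.09, adjusted p = 0.0388 and p = 0.654 with an estimated correlation) passed with it too (median 0.46, adjusted p = 0.00266). This call was lost with median centring and the deposited values, at 0.03 without labelled trastuzumab replicate 3, 0.02 and 0.07 without labelled NLS-L replicates 1 and 2. Normexp gave 0.30 for the interferon list.

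The remaining lists called for labelled NLS-L antibody against labelled trastuzumab did not pass with slide as a block. Antigen presentation had 2 of 22 higher, 11 adjusted over the list alone (median 0.42, adjusted p = 1.90e-07 and p = 0.243 with an estimated correlation), and a median of -0.02 with slide as a block (adjusted p = 0.705). Metallothioneins had 1 of 11 lower, and 1 higher and 7 lower adjusted over the list alone (median -0.78, mean -0.48, adjusted p = 7.00e-04 and p = 0.409 with an estimated correlation), and 0.20 with slide as a block (adjusted p = 0.210). The HER2 amplicon had 1 of 18 lower, 2 adjusted over the list alone (median -0.20, adjusted p = 0.0133 and p = 0.243 with an estimated correlation), 0.07 with slide as a block (adjusted p = 0.637). The list was lost at -0.15 without labelled trastuzumab replicate 1, -0.19 without labelled NLS-L replicate 3. FOXO targets (0.16, adjusted p = 0.00243), apoptosis regulators (0.12, adjusted p = 0.00321), cyclin-dependent kinase inhibitors (0.25, adjusted p = 0.00552) and mesenchymal genes (0.41, adjusted p = 0.0163) had medians of -0.12, 0.07, 0.15 and -0.04 with slide as a block (adjusted p = 0.121, 0.950, 0.224 and 0.864), and with normexp FOXO targets had 0.10 and mesenchymal genes 0.19. In the order given, adjusted p = 0.312, 0.153, 0.0746 and 0.409 with an estimated correlation. Their members passed in 2, 2, 0 and 0 cases, and in 5, 5, 2 and 1 adjusted over the list alone. The mesenchymal call was lost at 0.28 and 0.31 without labelled trastuzumab replicates 1 and 2, 0.41 without labelled NLS-L replicate 3. In all, 267 genes differed (150 higher and 117 lower). Median centring, which moved the median of all genes by 0.12, gave 91.5% higher and the deposited values 66.7%, in place of 56.2%. Without labelled trastuzumab replicate 2, 0 genes passed in limma (1633 at an unadjusted p under 0.05). The count was 57 without labelled trastuzumab replicate 1, and 17 and 43 without labelled NLS-L replicates 1 and 2. It was 562 with the replicate number as a block and 148 with slide as a block, of which 24 were among the 267, and no slide held both groups.

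For unlabelled NLS-L antibody against unlabelled trastuzumab, the effect of NLS-L without radiation, 0 genes passed in limma, with 391 at an unadjusted p under 0.05. TIMP1 had 1.26 ± 0.19, adjusted p = 0.112, and 1.75 with slide as a block (adjusted p = 0.00448). Small list shifts passed, with medians of 0.26 for the NF-kB list (25 of 28 positive, adjusted p = 3.46e-06), 0.17 for antigen presentation (20 of 22, adjusted p = 2.45e-05), 0.23 for interferon-stimulated genes (22 of 26, adjusted p = 3.90e-05) and 0.27 for mesenchymal genes (7 of 7, adjusted p = 0.0114). In this order, adjusted p = 0.463, 0.463, 0.463 and 0.489 with an estimated correlation. Cholesterol biosynthesis had -0.15 (19 of 24 negative, adjusted p = 3.90e-05 and p = 0.463 with an estimated correlation). No member passed over all genes, and 1 did adjusted over the list alone, in the NF-kB list. Blocked by slide, these 5 medians were -0.09, 0.06, 0.05, -0.04 and -0.08, and none passed (adjusted p = 0.885, 0.831, 0.607, 0.850 and 0.165). Normexp gave 0.17, 0.11 and 0.17 for the NF-kB, interferon and mesenchymal lists. The NF-kB call was lost at 0.06 without unlabelled NLS-L replicate 3, and the mesenchymal one at 0.19 and 0.25 without unlabelled trastuzumab replicates 1 and 2, 0.19 and 0.11 without unlabelled NLS-L replicates 2 and 3. G1/S and DNA replication (0.14, 38 of 43 positive, adjusted p = 0.0114 and p = 0.976 with an estimated correlation) and the unfolded protein response (-0.10, 26 of 31 negative, adjusted p = 0.0114 and p = 0.866 with an estimated correlation) turned to -0.20, a call of the opposite direction (adjusted p = 3.14e-05), and 0.17 (0.183) without unlabelled trastuzumab replicate 3. With slide as a block they stood at 0.77 and -0.56, but there unlabelled trastuzumab replicate 3 alone stands for its group. They were lost at 0.05 and -0.08 without unlabelled NLS-L replicate 1 and at 0.08 and -0.03 without its replicate 2. Median centring moved the median of all genes by -0.12 and ended the unfolded protein call. The number of changed genes was 79 with slide as a block and 213 with array weights, and only 1 trastuzumab array shared a slide with the NLS-L antibody.

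Some genes changed with all 4 antibody preparations. Called in each of the 4 comparisons were 36 higher genes, among them LCN2, PIGR, PLAAT4, KRT23, CEACAM6, TXNIP, INSR and SPRY4, and 17 lower genes, among them DIO2, FBP1, FAM25A and the glutathione transferases GSTM1 and GSTM3, whose probes can bind family members, where independent lists would share 3.37e-04 and 1.25e-04. Fewer were called without untreated replicates 1 (11 higher and 1 lower) and 2 (12 and 1), labelled trastuzumab replicates 1 (30 and 7), 2 (24 and 3) and 3 (23 and 4), and unlabelled trastuzumab replicates 1 (18 and 5) and 2 (28 and 5), and 42 and 29 without its replicate 3. The lower count was 10 or 11 without labelled NLS-L replicates 1 and 2 and unlabelled NLS-L replicates 1 and 3. Fold changes of both unlabelled antibodies correlated across genes at r = 0.812, against 0.599 in simulations of unchanged groups with the same controls and same-numbered arrays as correlated as measured, added after the data were seen, and 0.505 with independent arrays. The covariance was 0.0890 against 0.0267 simulated with correlated arrays. Both labelled antibodies had r = 0.751 against 0.635 and a covariance of 0.124 against 0.0351. Labelled NLS-L antibody and unlabelled trastuzumab had r = 0.511 against 0.597 and a covariance of 0.0826 against 0.0297. The other 3 pairs had r = 0.745, 0.768 and 0.651 (0.666, 0.621 and 0.570 simulated). As unchanged groups give few calls, the 0 shared in 20 simulations of either kind decides nothing. Part of the excess, in shared calls too, may come from these shared controls.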

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

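The tests of replicate number 3, the inflammatory list and the metallothioneins below were chosen only after these results were seen, and so were the settings with single slides, without replicate 3 and without the low-signal arrays. The difference between the label's effect on the NLS-L antibody and on trastuzumab passed camera for 9 lists. It was higher on the NLS-L antibody for NF-kB targets and secreted inflammatory factors (0.58, adjusted p = 5.66e-09, 26 of 28 members), interferon-stimulated genes (0.37, 2.99e-06, 20 of 26), antigen presentation (0.30, 0.0158, 16 of 22), FOXO targets (0.21, 0.00180, 22 of 25), cyclin-dependent kinase inhibitors (0.18, 0.0406, 16 of 20) and lysosomal genes (0.10, 0.0406, 20 of 29). In these 6 lists, adjusted p = 0.572 with an estimated correlation for antigen presentation and 0.346 for the others. It was lower for metallothioneins (-1.01, adjusted p = 1.09e-05, 8 of 11 members), the HER2 amplicon (-0.18, 0.0193, 13 of 18), whose median turned to 0.05 with median centring, and fatty acid synthesis (-0.15, 0.0157, 20 of 23), which turned to 0.08. Here adjusted p = 0.421 with an estimated correlation for fatty acid synthesis and 0.346 for the others. No member passed over all genes. With slide as a block the calls of the inflammatory, interferon, metallothionein and fatty acid lists held (0.46, 0.29, -0.65 and -0.15, adjusted p = 1.91e-05, 1.34e-04, 1.27e-04 and 0.00588). Those of antigen presentation, FOXO targets, kinase inhibitors, lysosome and HER2 amplicon gave 0.08, 0.10, 0.14, 0.11 and -0.07 (adjusted p = 0.240, 0.15, 0.0858, 0.0858 and 0.0665). Normexp ended the lysosome call, quantile scaling the lysosome and kinase inhibitor calls and median centring the HER2 amplicon one. The inflammatory, interferon and metallothionein calls held without any 1 array. The others were lost, antigen presentation at 0.21 and 0.20 without labelled trastuzumab replicates 1 and 2, 0.08 without unlabelled trastuzumab replicate 3, 0.27 and 0.21 without unlabelled NLS-L replicates 1 and 2. FOXO targets were lost at 0.10 without unlabelled trastuzumab replicate 3, and kinase inhibitors at 0.12 without labelled trastuzumab replicate 1, 0.14 without unlabelled trastuzumab replicate 3, 0.17 without labelled NLS-L replicate 3, 0.15 and 0.12 without unlabelled NLS-L replicates 1 and 2. Lysosomal genes were lost at 0.08 and 0.07 without labelled trastuzumab replicates 1 and 2, 0.09 and 0.11 without unlabelled trastuzumab replicates 2 and 3, 0.07 without labelled NLS-L replicate 1, 0.08 without unlabelled NLS-L replicate 2. The HER2 amplicon was lost at -0.08 without labelled trastuzumab replicate 1, -0.07 without unlabelled trastuzumab replicate 3, -0.14 without labelled NLS-L replicate 3, and fatty acid synthesis at -0.09 without labelled trastuzumab replicate 1, -0.12 without labelled NLS-L replicate 3, -0.07 without unlabelled NLS-L replicate 1.

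Each pairwise comparison of 3 against 3 arrays allows 10 splits, too few for a share under 0.05. In 6 of them 1 split, the real one, gave as many genes, with 0 as the highest other (real counts 891, 108, 2300, 102, 321 and 267). In the remaining comparisons, labelled against unlabelled trastuzumab and both unlabelled antibodies, the real split gave 0, as did all 10. Where numbers paired the arrays, 4 splits part all pairs, and the highest other among them was 0. For the difference of label effects, where the real split gave 0, all 100 of 100 drawn splits gave as many by construction, which decides nothing about chance. The highest gave 775, in splits that can part the antibodies.

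Replicate 3 arrays of the 4 antibody groups deviated from their group means together. Slide is argued against by labelled trastuzumab replicate 3, on slide 1, which correlated with the replicate 3 arrays of slide 2 at 0.432 on average, above every differently numbered pair of antibody arrays across slides (highest 0.346). Low signal is argued against by a lowest correlation of 0.261 among the replicate 3 arrays of ordinary signal. A shared experiment behind the number may be the source and stays open, since untreated replicate 3 correlated with the 4 arrays at 0.0881 at lowest and 0.193 at highest.

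NF-kB targets and secreted inflammatory factors were higher with the label on the NLS-L antibody. All 6 arrays lay on slide 2, so slide did not differ between these groups. Low array signal is argued against by a median of 1.18 without the low-signal arrays (adjusted p = 1.70e-17), and replicate number 3 by 1.35 without it in any group (adjusted p = 6.41e-28). A response of these genes to the radionuclide is a hypothesis consistent with these values, found and tested on the same data, and the list's adjusted p of 0.285 with an estimated correlation leaves a shared swing of its members open.

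Metallothioneins fell with the label on the NLS-L antibody (adjusted p = 0.00386, and 0.428 with an estimated correlation), both groups on slide 2. Against untreated cells, on another slide, labelled NLS-L had a median of -0.0079 (mean 0.22, 5 of 11 positive, adjusted p = 0.510). The other 3 had 0.74, 0.84 and 0.94. Blocked by slide, unlabelled NLS-L had 1.95, unlabelled and labelled trastuzumab 1.08 and 0.84, and labelled NLS-L lay 0.20 above the latter. The label in itself stays open, as labelled lay above unlabelled trastuzumab (0.10, adjusted p = 0.296) only unblocked. So does 1 transcript read by near-identical probes, as SLC30A1, a zinc exporter outside the family, had 0.69 (adjusted p = 0.0505). Metal carried by the preparations was not tested.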

How the results depend on the processing

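The settings with 1 slide alone, without replicate number 3 in all groups, and without both low-signal arrays (untreated replicate 2 and unlabelled NLS-L replicate 3) were chosen only after the data were seen, and the others in advance. Counts of changed genes are given in the order labelled against unlabelled NLS-L antibody, labelled trastuzumab, labelled NLS-L, unlabelled trastuzumab and unlabelled NLS-L against untreated, and labelled NLS-L against labelled trastuzumab (891, 108, 2300, 102, 321 and 267). An adjusted p of 0.01 gave 112, 20, 898, 19, 89 and 26, fewer by construction. Array weights gave 4912, 781, 4056, 697, 1915 and 2892. Without a probe filter, and so with more genes tested, the counts were 308, 28, 28, 146 and 65 in all but labelled NLS-L against untreated. Fits on only the arrays compared gave 373, 32, 5, 183 and 54 in the same 5. Median centring gave 52, 53 and 204 for labelled trastuzumab, unlabelled trastuzumab and unlabelled NLS-L antibody against untreated. Normexp gave 416 for labelled NLS-L against labelled trastuzumab, and trend and robust gave 166 for labelled trastuzumab against untreated. Slide as a block gave 1341, 230, 1227, 127, 278 and 148. Slide 2 alone gave 373 for the label on the NLS-L antibody, and slide 1 alone gave 44 for unlabelled trastuzumab against untreated. Without replicate number 3 the counts were 2070, 292, 2901, 422, 1003 and 1255. Without the low-signal arrays they were 750, 24, 1609, 15, 73 and 253. Filters on all arrays, quantile scaling, the deposited values, marked spots kept and the mean of a gene's probes left all 6 counts within 1.5 times. The cause of these shifts was not tested, save where a setting has fewer arrays or more genes.

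In limma, labelled against unlabelled trastuzumab gave 7 with array weights, and 0 in the other settings that kept all arrays. Unlabelled NLS-L against unlabelled trastuzumab gave 79 with slide as a block and 213 with array weights. The difference of both label effects gave 2 with normexp, 1 with median centring, 1 with probes above background on all arrays, 1 with trend and robust, 2 with slide as a block, 1055 with array weights and 17 without replicate number 3. These 3 held 604, 391 and 887 genes at an unadjusted p under 0.05. The correlation of both label effects was 0.226 without a probe filter and 0.806 over called genes alone, which are chosen for their size, and it lay between 0.30 and 0.54 with 1 array left out.

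With 1 array left out, counts ranged from 94 to 912 for the label on the NLS-L antibody, 22 to 83 for labelled trastuzumab, 1109 to 1828 for labelled NLS-L, 16 to 127 for unlabelled trastuzumab and 115 to 309 for unlabelled NLS-L antibody against untreated. They ranged from 0 to 396 for labelled NLS-L against labelled trastuzumab, 0 to 1 for the label on trastuzumab and for both unlabelled antibodies, and 0 to 3 for the difference of label effects. The lone pair left in a group was taken to vary like the other groups. Among called named genes, 1094 such values kept the call, 682 lost it and 0 reversed, and 32 values of other named genes passed. In labelled NLS-L against untreated 70 of 100 called genes kept the call without any 1 array, in the label on the NLS-L antibody 13 of 61, and in labelled NLS-L against labelled trastuzumab 0 of 40. Under other settings 7146 kept their side, 654 lost the call, 389 gained it and 4 reversed. These 4 were THRA in labelled NLS-L against untreated (0.079), GPER1 (0.087) and KANK4 (0.19) in unlabelled NLS-L against untreated, and MT1X in labelled NLS-L against labelled trastuzumab (0.030), each with slide as a block.

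List calls with 1 array left out were kept in 516 cases, lost in 90 and reversed in 6. The 6 lists reversed without unlabelled trastuzumab replicate 3, the array on which the slide block rests. For the label on trastuzumab, the medians with 1 array left out ran from -0.24 to 0.083 in the unfolded protein response and from -0.21 to 0.046 in NRF2 targets. Against untreated, unlabelled trastuzumab had -0.40 to 0.087 in G1/S and -0.54 to -0.019 in histones, where the test's direction reversed. Unlabelled NLS-L against unlabelled trastuzumab had -0.20 to 0.30 in G1/S and -0.22 to 0.17 in the unfolded protein response. Under other settings 1316 list values kept the call, 288 lost it, and 19 reversed. With slide as a block and from slide 1 alone, the unfolded protein response (0.083) and NRF2 targets (0.046) reversed for the label on trastuzumab, and G1/S (0.087) and histones (-0.019, by the test) for unlabelled trastuzumab against untreated. With slide as a block, FOXO targets reversed in labelled NLS-L (0.058, by the test) and unlabelled NLS-L (-0.16) against untreated and in labelled NLS-L against labelled trastuzumab (-0.12), where metallothioneins (0.20) and mesenchymal genes (-0.043) also did. For unlabelled NLS-L against unlabelled trastuzumab, antigen presentation (0.060, by the test) and mesenchymal genes (-0.038) reversed with it. G1/S reversed with array weights (0.015) and without replicate number 3 (0.094) in unlabelled trastuzumab against untreated, and likewise (-0.065 and -0.054) in unlabelled NLS-L against unlabelled trastuzumab. Of 93 list calls, 3 held with an estimated correlation, 38 with fry, which does not compare a list with other genes, 54 with slide as a block, 70 without replicate number 3, and between 75 and 92 in each of the other settings that kept all arrays. The cause was not tested.

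Where the replicate number paired the arrays, the replicate block gave 648 genes for unlabelled NLS-L against untreated and 562 for labelled NLS-L against labelled trastuzumab, and ended the fatty acid call of the label on trastuzumab (adjusted p = 0.0973). Where it did not pair them, the block gave 1521 for the label on the NLS-L antibody, 270, 3118 and 306 for labelled trastuzumab, labelled NLS-L and unlabelled trastuzumab against untreated. The correlations for numbers 1 to 3 were 0.291, 0.0364 and 0.308, then -0.0808, -0.117 and 0.0881, 0.0654, -0.128 and 0.0884, and 0.0359, 0.0753 and 0.193, and no such comparison had every array correlate best with its own number. Labelled against unlabelled trastuzumab, taken as paired, had this for number 3 alone. It ended 4 of 93 list calls, of which the fatty acid call alone lay where numbers paired, and ended no named gene there. The array signal limits values near background. Of 13105 genes tested, those dim in a group have bounds only, and CDKN1A, above background on 2 of 15 arrays, has no test.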

Other observations

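The lists of squamous and placental genes below, their members, and the values without single arrays, under other scalings and with slide as a block were chosen only after the largest changes were seen, as were the tests on them and the covariance of same-numbered deviations, whereas the test of the direction shared by both label effects was set before its result was seen. With the label on the NLS-L antibody, genes of squamous epithelium outside the fixed lists rose. KRT16, a keratin of stressed epidermis, rose by 2.50 ± 0.40 (limma, adjusted p = 0.00607), KRT5, a basal keratin, by 2.00 ± 0.31 (0.00522), and PI3, an elastase inhibitor of skin, by 1.63 ± 0.23 (0.00381). Genes of the placenta rose too, with PGF, a growth factor of the VEGF family, at 1.28 ± 0.17 (0.00284) and ALPG, a placental-like alkaline phosphatase, at 1.06 ± 0.18 (0.00896). Probes of ALPG and of the keratins can bind near-identical family members. These 5 calls held without any 1 array of the comparison, with a highest adjusted p from 0.0216 (PGF) to 0.0449 (ALPG).

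One hypothesis is that whole groups of squamous and placental genes rose, not only the members that drew attention. Of 55 genes in a keratinocyte and squamous list, 36 were measured and 12 were higher. The 32 that the rule had not named had a median of 0.73, with 8 higher and 28 positive. Camera adjusted over 36 tests gave p = 2.76e-08, and 0.0116 with an estimated correlation. Of 40 genes in a placental and trophoblast list, 20 were measured and 7 were higher. The 15 unnamed had a median of 1.28, with 3 higher and 13 positive (adjusted p = 5.33e-06, and 0.0207 with an estimated correlation). Without labelled NLS-L replicate 1, 9 of the 12 squamous and 3 of the 7 placental calls were lost. Both medians stayed positive and past camera without any 1 array (0.65 to 0.77, and 1.12 to 1.40) and with normexp and quantile scaling (0.41 and 0.59). Both lists were chosen after seeing these rises, some probes can bind several members, and dropping members dim in all groups can favour rises. The hypothesis stays open. With the label on trastuzumab, the unnamed squamous genes had 0.42 (27 of 32 positive, 0 past the threshold, adjusted p = 6.89e-08, and adjusted p = 0.0120 with an estimated correlation) and the unnamed placental genes 0.25 (adjusted p = 0.0780). With slide as a block these were 0.37 (adjusted p = 1.14e-08) and 0.24 (9.55e-04). Without a label, NLS-L against plain antibody gave the unnamed squamous genes 0.24 (28 of 32 positive, 0 past the threshold, adjusted p = 2.28e-07, and adjusted p = 0.0120 with an estimated correlation). These groups shared a slide through 1 array, and with slide as a block the call ended (0.26, adjusted p = 0.0780). The difference between both label effects was 0.28 (adjusted p = 0.00376, and 0.103 with an estimated correlation) and 0.69 (4.61e-05 and 0.0220).

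Another hypothesis is that the label on trastuzumab without NLS-L gave a weaker response of the same kind. Of the 891 genes changed by the label on the NLS-L antibody, 90.5% had the same sign with the label on trastuzumab, and the share was 83.05% at lowest without 1 array (labelled trastuzumab replicate 3), against 66.9% of all genes. This is consistent with the hypothesis, with a slope of 0.302 across genes (not independent), but swings that arrays share by chance also raise both values, and those of same-numbered arrays gave an estimated covariance of 7.21e-04, against 0.0443 measured. Relabelled arrays stay open, because only 10 splits exist, which cannot give a share under 0.05, where 1 split, the real one, gave as large a share and the highest other was 78.9%.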
